A study of Escherichia coli with 6 samples.

How the data were processed

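RNA was sequenced from Escherichia coli strain 8099 in 6 libraries, 3 from control cells and 3 from cells labelled with violet phosphorene nanosheets (VPNS) for 3 h. Groups came from the agent given in the labels, and replicate numbers from the sample titles. The labels give a time for the nanosheet libraries only. Per the labels' protocols, total RNA was extracted with a column kit for bacteria and libraries were made with a directional (strand-marking) kit. Nothing in the sources used here says whether the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

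The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to the size of the library), with 1 column per library. Per the submitters' processing notes, CASAVA 1.8, fastp, Bowtie2 2.2.3, HTSeq 0.6.1 and DESeq2 1.20.0 were used with the genome build ASM584v2. The notes give the tools no role or order, and whether reads were counted by strand is not given in the sources used here. That build is of another strain, K-12 MG1655, so genes that strain 8099 has and the build lacks were not measured. The table held 5084 features: 4639 genes with a b number, all of them matched to the reference gene table, 427 predicted transcripts and 18 predicted small RNAs. The table's gene length spans each gene from start to end. A total of 138 features had no read in any of the 6 libraries.

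The low values of the table show how the FPKM were made. Each value times the gene length was a whole multiple of 1 step per column: 100% of the 20433 values above 0 and under 200 steps lay within 0.02 of a whole number. The whole reads behind each value were taken from these steps. The implied library sizes equalled the median-of-ratios size factors of those reads times 3430807, the geometric mean of the assigned reads, in each library, so the deposited FPKM already held a scaling between libraries. Assigned reads per library were 3579271, 3538743 and 3050804 for control replicates 1 to 3 and 3647635, 3349427 and 3454125 for VPNS replicates 1 to 3. No 2 libraries were alike within sampling noise: the chi-square of their reads per degree of freedom was between 36.8 and 165.1 over the 15 pairs.

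The design was fixed before the data were examined: the tests, the other settings to be tried, the gene lists and the rule for named genes. The main test was limma 3.58.1 (linear model, empirical Bayes with a mean-variance trend) in R 4.3.3 on log2(FPKM + 1), for the 4676 features with a mean of at least 1 FPKM over the 6 libraries. Fold changes are on that log2(FPKM + 1) scale, VPNS minus control, which understates the change of low genes. A feature rose or fell where its Benjamini-Hochberg adjusted p was below 0.05. Values are given as mean ± SD with n = 3 per group. Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 43 lists with at least 3 tested members. The remaining list of the 44, ribosomal RNA, had no member past the filter. Camera compares a list with all other genes, and fry, also from limma, tests whether a list moves on balance one way. The count of members past the test was also adjusted over the list alone.

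The rule for named genes took the 8 largest rises and 8 largest falls among annotated genes past the test, with a mean of at least 10 FPKM and no overlap between the groups. It added, in each list called by camera, the 2 members with the smallest p in the list's direction. It also added 15 sentinel genes of stress responses whatever their values, which gave 40 genes in all. Genes named outside the rule are said to be so.

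Titles number the libraries 1 to 3 in both groups. The deviations of same-numbered libraries from their group means correlated at 0.34, 0.18 and 0.20 over features for numbers 1, 2 and 3, all above 0.1. Unlike-numbered libraries of the 2 groups correlated at -0.28 to 0.028. The numbers were therefore treated as possible pairs. The pairing comes from this check and not from a statement in the labels. Deviations sum to 0 within a group, so these values are tied to one another and the check is weak. The main fit stayed without the block, as set in advance. The planned fit with the replicate number as a block is given beside a result where it changed a call.

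Set in advance as other ways to process the values were pseudocounts of 0.1 and 5, no filter and a mean of at least 10 FPKM, 3 scalings (median of ratios, TPM and quantile), limma without the trend and with robust empirical Bayes, the block, each replicate left out in turn, camera with an estimated correlation, and fry. Added after the data were seen were voom, limma's model of read counts, on the recovered reads with and without the block, scaling to each library's assigned reads, the b-numbered genes alone, and the list tests that combine the block with an estimated correlation or fry. The count model set in advance for a table of raw counts was not run, because the table holds FPKM.

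The tests were tried on simulated reads for the same 4676 features and 3 against 3 libraries, with 200 features changed in each of 5 runs. The median dispersion was 0.0742. The limma test recovered 15.8% of changes of 2-fold, 88.7% of 4-fold and 98.5% of 8-fold, with 5.6 false calls per run. Voom recovered 37.9%, 97.9% and 100% with 4.8 false calls. A list with all members raised by 2-fold or more was called in 5 of 5 runs and an unmoved list in 0 of 5. The simulated features varied independently with 1 shared dispersion, while estimated correlations within real lists reached 0.869 (ribosomal proteins). These runs therefore do not show how often such lists are called without a change, and the recovery rates hold only for that setting. Plots were drawn with matplotlib 3.10.9.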

Results

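The transcriptome of Escherichia coli strain 8099 (a strain used in disinfectant tests) was compared between 3 control libraries and 3 libraries from cells given violet phosphorene nanosheets (VPNS), flakes of a layered form of phosphorus, for 3 h. The labels give no time for the controls, so a difference in incubation time cannot be told apart from an effect of the nanosheets. The series title asks about membrane penetration together with oxidative stress. Assigned reads per library ran from 3050804 to 3647635. Control replicate 3 stood apart: 5.06% of its features lay under 1 FPKM, against 15.2% to 17.3% in the other 5 libraries, and the first principal component (38% of the variance) set it off from the rest. A few stable RNAs took much of the reads. The transfer-messenger RNA ssrA, the RNase P RNA rnpB and the regulatory RNA csrB together took 29.4% ± 2.62 (SD, n = 3) of assigned reads in the controls and 37.1% ± 3.85 (n = 3) with nanosheets. The 2-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries can give. Alone, ssrA and rnpB also separated the groups, while csrB did not (4.37% ± 0.915 and 5.13% ± 0.795, exact permutation p = 0.5).

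**Figure D1:**
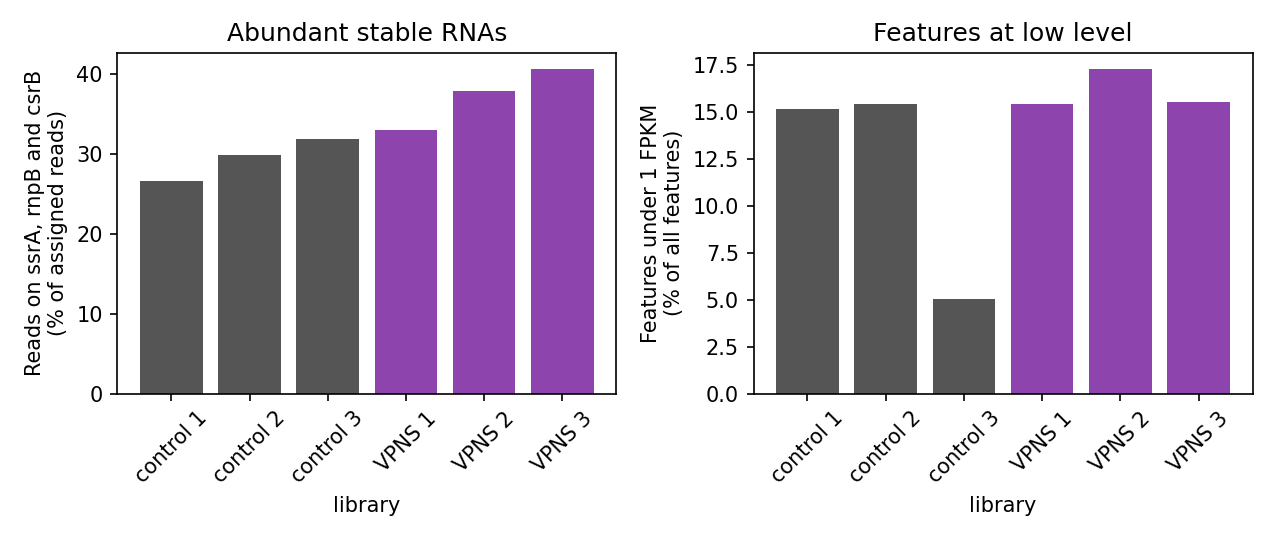
Left, reads on ssrA, rnpB and csrB as a percent of assigned reads per library; right, features under 1 FPKM as a percent of all features per library; gray bars are controls and purple bars VPNS, 1 bar per library. The share on the 3 RNAs is 31.8% or less in the controls and 32.9% or more with nanosheets, and control replicate 3 has 5.06% of features under 1 FPKM.

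With nanosheets 3 genes rose, each by over 2-fold. The universal stress protein gene uspD (b3923) went from 367.3 ± 32.9 FPKM in the controls to 10512 ± 2289 with nanosheets (log2 fold change 4.82, SE 0.26, adjusted p = 1.37e-04). Its upstream neighbour yiiS (b3922), of unknown function, went from 107 ± 29.6 to 1582 ± 524 FPKM (log2 fold change 3.87, SE 0.32, adjusted p = 0.00242). The membrane protein gene yeiH (b2158) went from 13.0 ± 3.23 to 484 ± 115 FPKM (log2 fold change 5.12, SE 0.28, adjusted p = 1.37e-04). The ratios of the group means were 28.6, 14.8 and 37.3, and each gene was higher in 3 of 3 nanosheet libraries than in every control. On the chromosome of ASM584v2, yiiS lies at 4112967 to 4113266 and uspD at 4113293 to 4113721, both on the plus strand with 26 bases between them, and yeiH lies at 2249717 to 2250766 on the plus strand. Whether counting used the strand is not given. A predicted transcript that lies opposite part of yeiH had a log2 fold change of 2.77 (limma adjusted p = 0.0518, by voom 0.0252). No feature fell (0 at adjusted p below 0.05 by limma and 0 by voom on the recovered reads). At an unadjusted p below 0.05, 145 features were higher and 209 lower of 4676 tested. With the replicate number as a block, 32 features rose and 3 fell, and voom called 17 higher. The 3 genes were among the calls of both. Leaving out VPNS replicate 1 gave 22 higher and 1 lower, while without control replicate 3 the adjusted p of yiiS was 0.0829 (log2 fold change 3.64).

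**Figure D2:**
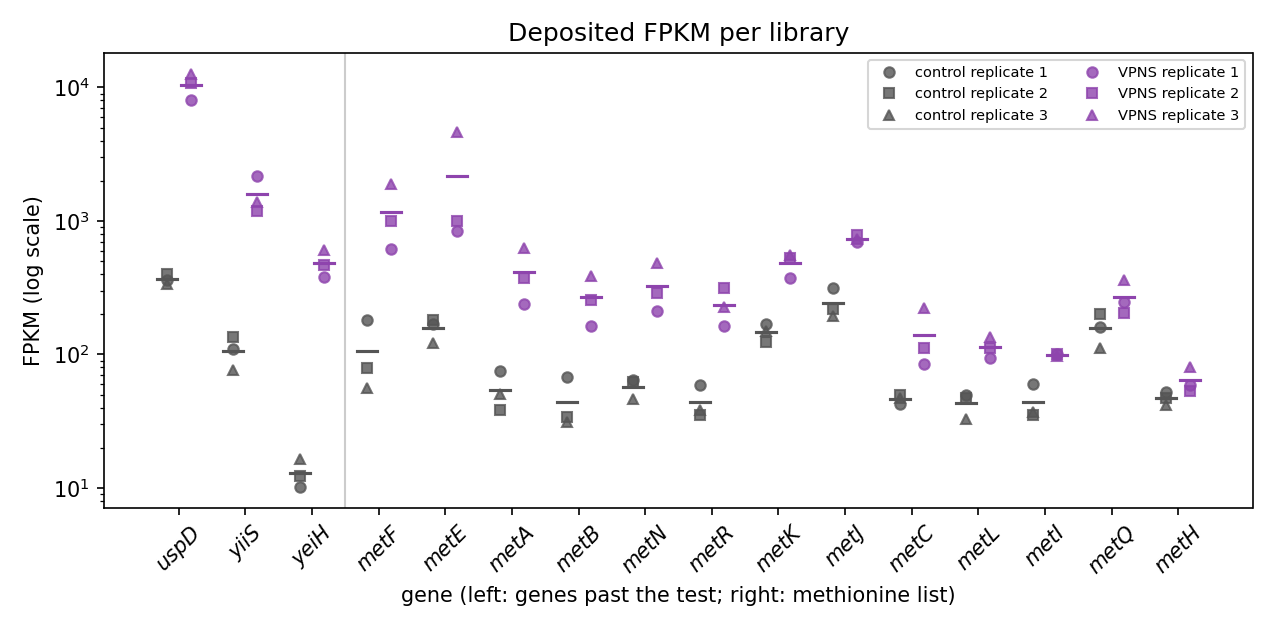
FPKM on a log axis for each library of uspD, yiiS, yeiH and the 13 members of the methionine list; gray marks are controls, purple marks VPNS, the shape gives the replicate number and the bar the mean of the 3 libraries. The nanosheet means of uspD, yiiS and yeiH are 10512, 1582 and 484 FPKM, and every methionine gene is higher in all 3 nanosheet libraries than in all 3 controls.

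Genes of methionine synthesis and uptake were higher together. In all 13 tested members the 3 nanosheet values lay above the 3 control values, and the median log2 fold change was 1.70 (range 0.43 to 3.48). Chance gives 5% of features in 1 direction, and in these data 345 of 4676 were higher in this way. The members move together (estimated correlation 0.575), so neither share is a baseline for all 13. The transporter gene metN went from 57.5 ± 9.46 to 328 ± 140 FPKM (log2 fold change 2.42, SE 0.33, adjusted p = 0.0518) and the activator gene metR from 44.2 ± 13.3 to 235 ± 77.5 FPKM (log2 fold change 2.37, SE 0.33, adjusted p = 0.0518). Adjusted over all features 0 of the 13 rose by limma on log2(FPKM + 1) and 8 by voom on the recovered reads, and adjusted over the list alone 12 rose by limma. Voom (adjusted p = 0.0209 for both), robust empirical Bayes (0.0448) and the test of b-numbered genes alone (0.0464) called metN and metR. With the replicate block 8 of the 13 rose over all features, metN (adjusted p = 0.0196) and metR (adjusted p = 0.0216) among them. Camera called the list higher (adjusted p = 6.31e-24), with an adjusted p = 0.488 with an estimated correlation.

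Of the envelope stress lists, phage shock and Cpx were called higher, and sigma-E (28 members, median 0.15, camera adjusted p = 0.168) and Rcs with capsule (23 members, median -0.35, adjusted p = 0.264) were not. The phage shock list, which guards the inner membrane, had a median log2 fold change of 1.65 over 7 members (camera adjusted p = 4.11e-04, adjusted p = 0.726 with an estimated correlation). Its members pspA (1556 ± 1012 to 5355 ± 3680 FPKM, log2 fold change 1.77) and pspC (394 ± 231 to 1355 ± 875 FPKM, log2 fold change 1.75) were higher without overlap, at adjusted p = 0.505 and 0.480. With the replicate block pspA and pspC rose (adjusted p = 0.0175 and 0.0129), as did 4 of the 7 members, and fry with the block called the list (adjusted p = 0.0464). Adjusted over the list alone, 4 members rose without the block. In the Cpx list (12 members, camera adjusted p = 0.0276, adjusted p = 0.726 with an estimated correlation) the median was 0.27, but -0.36 after TPM scaling and -0.24 after scaling to assigned reads, where the list was still called higher relative to all features (adjusted p = 0.0361 and 0.0248). The periplasmic chaperone gene spy went from 161 ± 34.6 to 650.4 ± 170.3 FPKM (log2 fold change 1.99, adjusted p = 0.0597, with the block 0.0129, by voom 0.0252), and was the 1 member of the list to rise adjusted over the list alone. The other named members were cpxP (log2 fold change 0.95) and degP (-0.08). The Cpx call was lost without control replicate 1 (median 0.35, adjusted p = 0.0694), control replicate 3 (0.12, adjusted p = 0.225) or VPNS replicate 3 (0.21, adjusted p = 0.252), under quantile normalization (0.05, adjusted p = 0.759) and at a mean of at least 10 FPKM (adjusted p = 0.229). All 21 tested heat shock genes had positive fold changes (median 0.67, camera adjusted p = 9e-04, adjusted p = 0.811 with an estimated correlation), though 0 rose adjusted over the list alone. The sigma factor gene rpoH had a log2 fold change of 0.74 and hslR of 0.53 (-0.10 after TPM scaling). The small heat shock gene ibpA stood at 134, 2939 and 1264 FPKM in control replicates 1 to 3 and at 128, 5188 and 1013 in VPNS replicates 1 to 3. In fits without the block the median of the list hung on single libraries. The call of the list was lost without control replicate 1 (median 0.23, adjusted p = 0.112), control replicate 3 (0.48, adjusted p = 0.133) or VPNS replicate 2 (0.24, adjusted p = 0.205), and under quantile normalization (0.39, adjusted p = 0.211). With the block camera called the list (adjusted p = 1.07e-08), but not with an estimated correlation (adjusted p = 0.776).

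Oxidative stress lists moved little. The OxyR list, of the peroxide response, was called higher by camera (20 members, adjusted p = 0.0276, adjusted p = 0.713 with an estimated correlation) with a median of 0.20, which lay below 0 under TPM, quantile and assigned-read scaling. Its highest named members were the DNA-binding protein gene dps (10021 ± 1806 to 15260 ± 836 FPKM, log2 fold change 0.62) and the peroxidase gene ahpC (1655 ± 257 to 2404 ± 450 FPKM, log2 fold change 0.53), both without overlap between groups. Under TPM scaling their values were -0.02 and -0.10, above the -0.59 of all features, and dps was at -0.11 under quantile normalization. The catalase gene katG had a log2 fold change of -0.16 and the glutaredoxin gene grxA of -0.12. The SoxRS list (20 members, median 0.03, camera adjusted p = 0.685) and the list of superoxide and peroxide scavenging enzymes (12 members, median 0.05, camera adjusted p = 0.696) were not called. In the SoxRS list 1 member rose adjusted over the list alone, the flavodoxin reductase gene fpr (69.1 ± 14.0 to 296 ± 147 FPKM, log2 fold change 1.98, adjusted p = 0.142, with the block 0.0185). It was named after its values were seen, and it lies opposite uspD with 4 bases between their ends. The regulator gene soxS had a log2 fold change of 0.24, and the superoxide dismutase gene sodA was lower without overlap (151 ± 9.82 to 66.0 ± 40.4 FPKM, log2 fold change -1.39, adjusted p = 0.521). The more abundant dismutase gene sodB, named after its values were seen, was higher without overlap (2206 ± 125 to 3586 ± 682 FPKM, log2 fold change 0.69, adjusted p = 0.603). The RpoS list was called higher (27 members, median 0.26, camera adjusted p = 0.00488, adjusted p = 0.811 with an estimated correlation), with a median below 0 under TPM, quantile and assigned-read scaling. Its second named member, osmE, had a log2 fold change of 0.72. No member of the OxyR or RpoS list rose or fell adjusted over the list alone. The OxyR call was lost without control replicate 1 (median 0.21, adjusted p = 0.0765), control replicate 3 (0.15, adjusted p = 0.133) or VPNS replicate 1 (0.12, adjusted p = 0.181). The RpoS call was lost without control replicate 3, which left a median of 0.016 (adjusted p = 0.714), or VPNS replicate 1 (0.23, adjusted p = 0.181). Both were also lost under TPM (adjusted p = 0.66 and 0.164), quantile (0.759 and 0.795) and assigned-read scaling (0.531 and 0.0757), and at a mean of at least 10 FPKM (0.189 and 0.119). The SOS list of DNA damage genes was not called (28 members, median -0.02, camera adjusted p = 0.916), with recA at 0.08 and sulA at -0.13.

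Anaerobic respiration and fermentation genes were called higher by camera (56 members, adjusted p = 6.71e-05, adjusted p = 0.488 with an estimated correlation), although the median was only 0.15 and turned to -0.43 and -0.35 under TPM and assigned-read scaling, where the list was still called (adjusted p = 1.16e-04 and 6.52e-05) against medians of all features of -0.59 and -0.52. The members went both ways, 37 positive and 19 negative. The 2 named members belong to nitrate reductase A: narG went from 48.1 ± 6.99 to 145 ± 21.0 FPKM (log2 fold change 1.57, adjusted p = 0.0597, with the block 0.0242, by voom 0.0295) and narI from 57.6 ± 2.42 to 141 ± 27.6 FPKM (log2 fold change 1.26, adjusted p = 0.129). Adjusted over the list alone 5 members rose, and 2 of 56 rose over all features with the block. The call held with each library left out in turn.

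Iron acquisition, surface fiber and toxin-antitoxin lists were called lower. The iron list had 38 of 43 members with negative fold changes (median -0.59, camera adjusted p = 4.11e-04, adjusted p = 0.789 with an estimated correlation), and none fell adjusted over the list alone. The ferric reductase gene fhuF went from 48.8 ± 28.8 to 12.8 ± 6.77 FPKM (log2 fold change -1.85), and the enterobactin receptor gene fepA had a log2 fold change of -0.36. The gene bfd overlapped between the groups, with 13, 10 and 4 reads in the controls and 4, 0 and 0 with nanosheets. The iron call was lost without VPNS replicate 3 (median -0.32, adjusted p = 0.0809) and under quantile normalization (-0.03, adjusted p = 0.241). It was also lost under TPM (-0.72, adjusted p = 0.282) and assigned-read scaling (-0.91, adjusted p = 0.096), where the median was lower but all features fell too (-0.59 and -0.52). The list of curli, fimbriae and biofilm matrix (21 members, median -0.51, camera adjusted p = 0.00454, adjusted p = 0.766 with an estimated correlation) had 1 member that fell adjusted over the list alone. This was the curli gene csgF, with 6 to 13 reads in the controls and 0, 1 and 0 with nanosheets, and the recombinase gene fimB had a log2 fold change of -1.35. With the block 0 members fell adjusted over the list alone. The camera call of the list was lost without control replicate 3 (median -0.36, adjusted p = 0.133), under TPM (-0.84, adjusted p = 0.385) and assigned-read scaling (-0.92, adjusted p = 0.213), under quantile normalization (-0.09, adjusted p = 0.37), and among features with a mean of at least 10 FPKM (-0.66, adjusted p = 0.23). In the toxin-antitoxin list 17 of 20 members were negative (median -0.35, camera adjusted p = 0.00488, adjusted p = 0.663 with an estimated correlation), with the antitoxin genes higA at -1.16 (26.0 ± 6.75 to 11.1 ± 3.02 FPKM) and yafN at -1.97. None fell adjusted over the list alone, and the call held with each library left out. Protein-coding genes with 1 to 5 FPKM in control replicates 1 and 2 were higher in control replicate 3 by a median of 3.36 FPKM (736 genes).

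Translation genes and stable RNAs were called slightly higher. Aminoacyl-tRNA synthetase genes had positive fold changes in 21 of 23 members (median 0.35, camera adjusted p = 5.77e-04, adjusted p = 0.726 with an estimated correlation), with ileS at 0.67 and metG at 0.51 (-0.12 under TPM scaling), but the median was -0.28 and -0.16 under TPM and assigned-read scaling. That call was lost under both (adjusted p = 0.445 and 0.213) and under quantile normalization (0.0996). Ribosomal protein genes had a median of 0.27 over 54 members (camera adjusted p = 0.0256, adjusted p = 0.918 with an estimated correlation), with rpmA at 0.43 and rpsT at 0.60 (-0.20 and -0.03 under TPM scaling), and the median lay below 0 under TPM, quantile and assigned-read scaling. Camera called the list under TPM and assigned-read scaling (adjusted p = 1.16e-04 and 4.16e-04), where its median lay above that of all features, but not under quantile normalization (0.97) or at a mean of at least 10 FPKM (0.467). The call was lost without control replicate 2 (median 0.16, adjusted p = 0.0662), and the median was -0.32 without control replicate 3 (adjusted p = 0.516) and -0.31 without VPNS replicate 1 (0.382). The 4 stable RNAs of the RNA composition check had a median of 0.82 (camera adjusted p = 0.0151, adjusted p = 0.726 with an estimated correlation), with rnpB at 0.85 and ssrS at 0.80. That call was lost without control replicate 3 (median 0.80, adjusted p = 0.102) or VPNS replicate 3 (0.55, adjusted p = 0.174). Quantile normalization gave 0.06 (adjusted p = 0.649), but it sets the most abundant features equal across libraries and so cannot show a change in them. Adjusted over each of these lists alone, 0 members rose or fell. The share of reads on ssrA and rnpB moved with the groups, as given above.

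**Figure D3:**
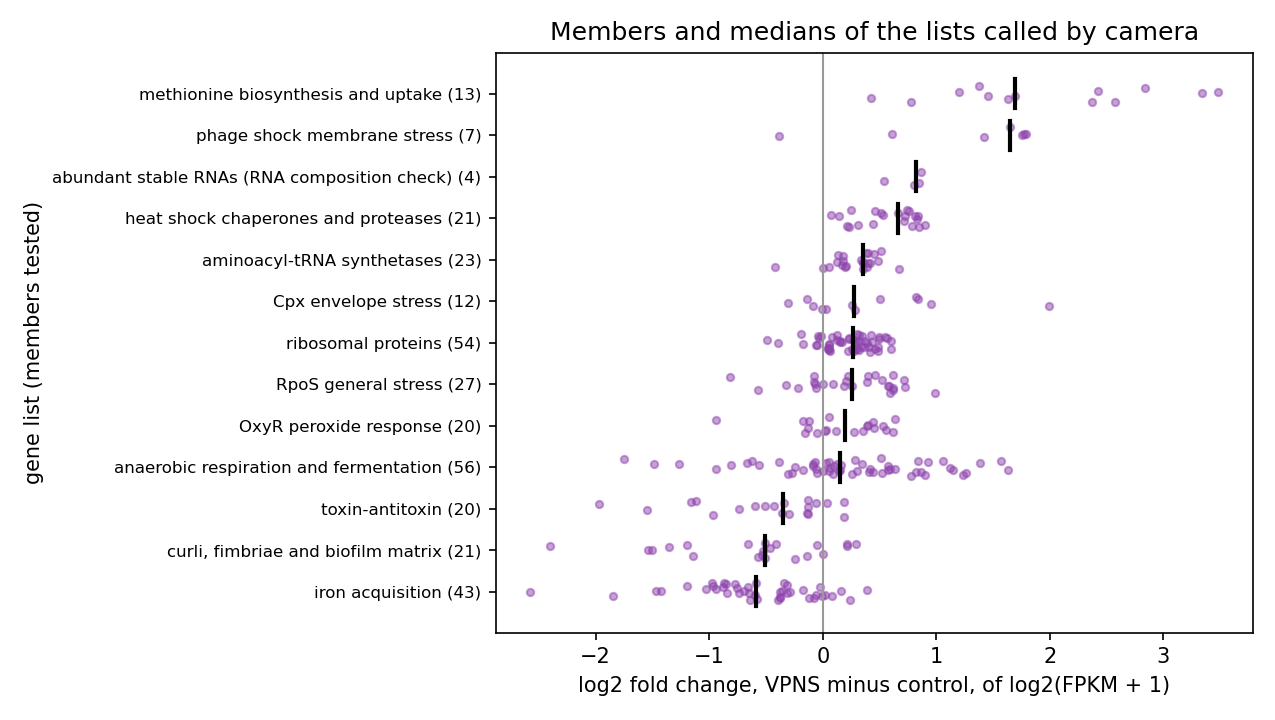
Log2 fold change, VPNS minus control, of each tested member (points, spread at random in height) and the median (bar) of the 13 lists called by camera, with the number of members tested. The methionine and phage shock medians are 1.70 and 1.65, and the iron list has the lowest median, -0.59; under TPM scaling the median of all features is -0.59 and the medians of 6 lists near 0 turn negative.

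The other 30 lists were not called, at camera adjusted p from 0.0735 up. Among them, besides those given above, were phosphate starvation (32 members, median -0.17, adjusted p = 0.685), copper and zinc homeostasis (18 members, median 0.12, adjusted p = 0.15), and multidrug efflux and Mar (25 members, median 0.01, adjusted p = 0.264). The phosphate-binding protein gene pstS had a log2 fold change of 0.02 and the regulator gene marA of 0.25, and rcsA had 10 reads or fewer in each library. None of the 15 sentinel genes passed the test without the block. Of the 13 called lists 0 were called with an estimated correlation and 0 with fry without the block. TPM and assigned-read scaling moved the median of all features from -0.05 to -0.59 and -0.52, and relative to these shifts the lists whose medians turned negative stayed above the median of all features.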

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

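The tests with voom, with assigned-read scaling, on b-numbered genes alone, and of lists with the block and an estimated correlation or fry were chosen after the data were seen. uspD and yeiH rose under every alternative run (log2 fold change 4.17 to 4.99 and 4.42 to 5.29), and yiiS under all but the one without control replicate 3 (3.22 to 4.06 over all). The counts of features higher and lower moved more. Against 3 higher and 0 lower, the replicate block gave 32 and 3, voom 17 and 0, voom with the replicate block 55 and 16 (53 and 16 by at least 2-fold), robust empirical Bayes 7 and 0, and b-numbered genes alone 6 and 0. Leaving out 1 library gave 2 to 22 higher and 0 to 1 lower, by at least 2-fold as well. The higher share of calls was 91.4% with the block and 77.5% with voom and the block, against 100%. All 3 main calls were among the 35 blocked calls, as were all 17 of voom. The cause of these differences was not tested. Median-of-ratios scaling moved nothing, because the deposited values already held it. Against 13 lists, 0 were called with an estimated correlation (with the replicate block also 0), 0 with fry and 1 with fry and the replicate block. Leaving out 1 library gave 9 to 16 lists. Of the 13 calls, 5 were lost at a mean of at least 10 FPKM (Cpx, curli, OxyR, ribosomal and RpoS), and the calls of iron, curli, aminoacyl-tRNA synthetases, OxyR and RpoS were lost under each of the TPM, assigned-read and quantile scalings. Camera with the block called 13 lists and, of the named genes, the block added narG, spy, metN, metR, pspA and pspC. It changed no other call of a named gene over all features and no called list. The methionine, phage shock and toxin-antitoxin lists were called under all 6 leave-one-out fits and all 3 other scalings that moved values. The TPM and assigned-read scalings lower nearly all features alike, which by itself turns small positive values. Under TPM scaling the log2 fold changes were -0.12 for metG, -0.10 for hslR, -0.0172 for dps, -0.10 for ahpC, -0.20 for rpmA, -0.0277 for rpsT, -0.39 for soxS, -0.55 for recA, -0.49 for ibpA, -0.26 for marA and -0.59 for pstS. The list medians were -0.28 for aminoacyl-tRNA synthetases, -0.43 for anaerobic respiration, -0.36 for Cpx, -0.42 for OxyR, -0.37 for ribosomal proteins and -0.38 for RpoS. Under assigned-read scaling the values were -0.00186 for metG, -0.0836 for rpmA, -0.27 for soxS, -0.44 for recA, -0.37 for ibpA, -0.18 for marA and -0.48 for pstS. The same 6 lists then had medians of -0.16, -0.35, -0.24, -0.31, -0.25 and -0.26. Quantile normalization gave -0.11 for dps, -0.13 for recA, -0.15 for ibpA, 0.12 for fepA and -0.0515 for pstS, and list medians of -0.00940 for OxyR, -0.00947 for ribosomal proteins and -0.014 for RpoS; the cause was not tested. Leaving out 1 library in turn, katG ran from -0.34 to 0.01998, soxS from -0.14 to 0.50, grxA from -0.39 to 0.0846, recA from -0.20 to 0.26, degP from -0.74 to 0.30, ibpA from -1.14 to 1.53, marA from -0.0564 to 0.59, pstS from -0.19 to 0.42 and the ribosomal median from -0.32 to 0.76. With 3050804 to 3647635 assigned reads per library, csgF, bfd, yafN and rcsA rest on a few reads in each library.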

Other observations

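The gene groups of the first 2 paragraphs, the test of the MetJ repressor, that of sulfur compounds, that of the label of control replicate 3, the division of genes at 0 FPKM and the share of reads on 3 RNAs were chosen after the results were seen. A group of 16 genes held genes of purine synthesis, the repressor gene purR (log2 fold change -0.49) and cvpA (-0.79), which lies next to purF. Of the 16, 10 were lower in all 3 nanosheet libraries than in all 3 controls, purR and cvpA among them. Chance gives 5% of features in 1 direction, and in these data 364 of 4676 were lower in this way. The group was chosen after the results were seen and holds neighbouring genes, such as purE and purK. Neither share is therefore a baseline for the 10. The median log2 fold change was -0.75. By voom 0 fell without the block, and purM, purT, purH and purC fell with it (adjusted p = 0.00107, 0.0104, 0.00874 and 0.0412). The fold changes of 3 were positive (purA 0.24, guaA 0.41 and purB 0.43). By limma 0 of the 16 fell over all features and 2 fell with the replicate block. The 2 were purM and purT: purM went from 59.0 ± 30.9 to 9.70 ± 2.93 FPKM (log2 fold change -2.41, limma adjusted p = 0.0636, with the replicate block 0.0175) and purT from 16.2 ± 7.91 to 2.73 ± 1.25 FPKM (-2.17, adjusted p = 0.15, with the block 0.0382). The cluster of purine and ureide breakdown genes was negative in 16 of 16 tested members (median -1.20), with 3 below all controls. By limma 0 passed the test over all features with or without the block. Adjusted over the list alone, 5 fell by limma and 10 with the block. Voom with the block called ygeY (adjusted p = 0.00874) and ygeX (adjusted p = 0.0216) lower over all features.

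Zinc-responsive and Bae-controlled envelope genes were higher in 6 of 11 tested members without overlap. Of all features, 345 of 4676 were higher in this way. The group was chosen after the results were seen and holds neighbouring genes, so this share is no baseline. The median was 0.64, and 0.016 under TPM scaling, where that of all features was -0.59. Besides zraP, zraS and spy, the 6 were mdtA (log2 fold change 1.07), acrD (0.94) and mdtC (0.28). The reads of mdtC were 44, 45 and 53 in the controls and 66, 38 and 32 with nanosheets. The rest overlapped: zraR (0.64), mdtB (0.44), mdtD (0.05), baeR (0.01) and baeS (-0.30). By limma 0 of the 11 rose over all features without the block and 3 with it. By voom without the block 2 rose, zraS (adjusted p = 0.043) and spy (adjusted p = 0.0252). The periplasmic zinc-binding protein gene zraP went from 4291 ± 1790 to 16729 ± 6966 FPKM (log2 fold change 1.97, adjusted p = 0.213, with the block 0.0196), and the sensor kinase gene zraS from 42.6 ± 14.2 to 183 ± 66.3 FPKM (2.06, adjusted p = 0.0773, with the block 0.0175). Among 7 universal stress protein genes uspD alone rose, and the other 6 had log2 fold changes between -0.07 and 0.58. The gene fpr, on the strand opposite uspD with 4 bases between their ends, had a log2 fold change of 1.98 (adjusted p = 0.142, with the block 0.0185). All 8 predicted features among the blocked calls lay opposite a gene that was itself called with the block.

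Control replicate 3 had few features at low level, 206 with 0 reads against 434 to 615 in the other libraries, although it had the fewest assigned reads. A uniform background of reads in this library may account for it. Protein-coding genes under 1 FPKM in control replicates 1 and 2 were higher in it by a median of 2.68 FPKM and genes at 1 to 5 FPKM by 3.36, a ratio of 1.26 by which the explanation was judged, while no other library stood more than 0.063 FPKM above the rest of its group at 1 to 5 FPKM. That ratio covers only the lowest levels. The median gain was 2.47 at 5 to 10 FPKM, 0.82 at 10 to 30 and -6.24 at 30 to 100, which an equal gain at every level would not give. Within the lowest level the gain was uneven: 345 genes above 0 FPKM in control replicates 1 and 2 gained a median of 3.44 and 193 genes at 0 gained 0.55, and of these 193 the 84 with a read in a nanosheet library stood at 2.62 FPKM while 72 had 0 reads in all 6 libraries, which may be missing from this strain and so say nothing about a background. Whether genomic DNA was the source cannot be told apart: antisense predicted transcripts at 1 to 5 FPKM gained 1.43 times as much as the genes, but at 5 to 10 FPKM they gained 1.12 (15 transcripts) against 2.47 and at 10 to 30 FPKM -1.17 (129) against 0.82, and at 1 to 5 FPKM such transcripts also stood 1.14 and 1.68 FPKM above the other libraries of their group in VPNS replicates 1 and 2, where the genes gained 0.063 and -0.28, and the ratio rests on 14 transcripts (95% bootstrap interval 0.67 to 2.5); the interval and a limit of 20 transcripts for a verdict were added after the ratio was seen, which had met the bounds set before. Whether control replicate 3 is a mislabelled nanosheet library cannot be decided from uspD, yeiH and yiiS. All 3 lay nearer to the other controls in control replicate 3, but they were called with that library counted as a control. A difference of that culture was not tested.

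The methionine genes may be released from their repressor MetJ: of 6 genes reported under MetJ but outside the list, 4 (ybdL, hcxA, mmuP and mmuM) were higher in all 3 nanosheet libraries than in all 3 controls, with log2 fold changes of 0.63 to 2.61, while folE (-0.06) and yeiB (-0.11) were not. The genes are neighbours in pairs (ybdL with hcxA, mmuP with mmuM, folE with yeiB), so they do not count as 6 separate cases. The group was chosen after the results were seen, and ybdL and hcxA are among the calls by voom and with the block. It is therefore not an independent test of the repressor. The repressor gene metJ, named after its values were seen, was itself higher without overlap. It went from 242 ± 64.2 to 737 ± 42.8 FPKM (log2 fold change 1.63, limma adjusted p = 0.0597, with the block 0.0236, by voom 0.0328). The activator gene metR was also higher (log2 fold change 2.37), and a part of the activator in the rise was not tested. The tables argue against the scaling as the cause, as the list's own median was 1.055 under TPM, 1.179 under assigned-read and 1.485 under quantile scaling. It lay at least 1.48 above that of all features under each scaling. TPM and assigned-read scaling move nearly all features alike, so that difference could hardly change under them and says little there. The tables also argue against a single library, as the list's median was at least 1.58 with any 1 library left out. A general shortage of sulfur compounds is not what the sulfate and cysteine list shows, with a median of -0.133 (SD 0.67 over 25 members) against 1.70. What would release the repressor, and whether the nanosheets act on methionine itself, stays open.

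The share of reads on ssrA, rnpB and csrB was higher with nanosheets, carried by ssrA and rnpB, as csrB alone overlapped (4.37% ± 0.915 and 5.13% ± 0.795, exact permutation p = 0.5). The authors' scaling does not change this share, and the lowest nanosheet library lay 1.14 percentage points above the highest control. A bias toward short genes could raise such RNAs, but protein-coding genes under 300 nt differed from those of 900 nt and longer by a median log2 of 0.0315 (95% bootstrap interval -0.016 to 0.11). A change of these RNAs with nanosheets and a difference in how well ribosomal RNA or short RNA was removed from each library stay open, both untested.

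The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 3 features higher and the highest other 5, and 2 of the 10 splits gave as many. For features lower the real value was 0, which all 10 reached; which side of another split counts as lower is arbitrary, so its larger direction was taken, at most 5. The counts by at least 2-fold were the same. For lists the real value was 13 and the highest other 15, with 2 of the 10 at least as high. Of the 4 splits that part all 3 replicate numbers, the real one gave 3 features and 13 lists, and the others 0 features each and 5, 10 and 4 lists. These 4 are fewer still and rest on a pairing that the labels do not state, so they decide nothing.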
